A study of Callithrix jacchus and Rattus norvegicus and Loxodonta africana with 31 samples.

How the data were processed

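The series holds RNA sequencing of male and female tissues from mammals in which Y-linked genes had been reconstructed. It comprises 31 samples of 4 species: 14 from the common marmoset, a New World monkey, 12 from the rat, 2 from a wallaby, a marsupial, and 3 from the elephant. Polyadenylated RNA was sequenced, per the labels' protocols. The marmoset libraries were strand-specific and read for 101 cycles, except those of testis individual 2, which were read for 79 cycles on another sequencer. The 3 elephant fibroblast samples were not used here.

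Per the submitters' processing notes, TopHat 1.4.0 and Cufflinks 2.0.0 were used. The genome builds, annotations and filters are not given in the sources used here, so no coordinates are printed. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) by the authors, in one table per species, which per the file names were normalized across tissues by a method not given in the sources used here. The tables list Ensembl gene IDs together with Y-linked genes under the authors' own names. Each table was analysed on its own, and levels set side by side across species come from separately normalized tables.

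A table column was used only where its name matched the labels of 1 sample or group. The somatic libraries used were heart, kidney and liver of 1 male and 1 female in the marmoset and the rat, so 6 per species in place of the 10 that the design had assumed. Columns named for brain fit both the frontal cortex and the cerebellum samples and were not used. In all, 12 columns of per-sample values were not used, of which 4 held any value above 0. Frontal cortex and cerebellum results were therefore not computed. The marmoset testis has 1 column for 3 samples of 2 individuals. It is given as the authors' value, with no SD and no n. The wallaby columns used were liver and testis, both male.

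The marmoset table had 19681 genes, of which 7900 carried a symbol in the file, 6187 were named from an Ensembl name table and 5594 had no symbol. The rat table had 20486 genes, 18358 with a symbol in the file and 2128 without one. The wallaby table had 13892 genes, 12191 with a symbol in the file and 1701 without one. A RefSeq gene table of the marmoset assembly calJac240_pri was used for names and gene spans only. Genes marked by the authors as Y-linked numbered 29 in the marmoset and 12 in the rat.

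FPKM tables without counts do not give the sequencing depth. Low values showed no steps from which whole reads could be recovered (at most 1.19% of the low genes fell in the fullest bin of their ratio between testis and liver), so the depth is unknown and no counting interval can be given. An exact 0 in these tables can be a failed estimate. ALB, the albumin gene, was listed at 0 in the liver of both sexes of the marmoset and the rat. In the male marmoset liver HP, SERPINA1, FGA, FGB and FGG were listed at 0 as well, and in both rat hearts the mitochondrial genes MTCO3, MT-ATP6, ATP8 and COX1. A gene at 0 is therefore described only as listed at 0, and no fold is given against a group in which every library is at 0. Some of the folds given are against groups in which part of the libraries are at 0, and these depend on the pseudocount.

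Tissues were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). A fold change on this scale understates the change of genes near 1 FPKM. Genes with at least 1 FPKM in at least 2 libraries of the fit were tested. Each tissue was set against the mean of the other two, with the animal, which is also the sex, as a block. The pairing comes from the labels, which give heart, kidney and liver of a sex the same individual number. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. With 1 male and 1 female per tissue, the p-values measure the spread between these libraries after removal of a shared animal difference, with 2 residual degrees of freedom per gene before the spread is shared across genes. The marmoset testis column was set against the mean of the 3 somatic tissues in a fit of its own, in which the lone column is assumed to vary like the other libraries. The block there is sex and not the animal, since 2 of the 3 testis samples come from a second male. There the filter was at least 1 FPKM in at least 1 library, changed from 2 because testis has 1 column.

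Rat testis, the ovaries, the wallaby tissues and the sexes had 1 library per group, and no p-value is given for them. In rat testis and in ovary, genes were counted that lay at least 2 log2 units above or below every heart, kidney and liver library. In the wallaby, the threshold was a difference of 2 between testis and liver with at least 5 FPKM in the higher. For the sexes it was a difference of at least 1 in the same direction in each of the 3 tissues, and of at least 2 within a tissue. Tissue specificity of Y-linked genes over the male tissues was measured with tau, which is 0 for an even level and 1 for a single tissue, and genes at 0.8 or above are called testis-restricted where testis was the highest.

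The 33 gene lists were fixed before the data were examined. They covered Y-linked genes, their X partners, the X inactivation RNAs XIST and RSX, cortical neurons, synapses of neurons, cerebellar neurons, astrocytes, myelin, cardiac muscle, oxidative phosphorylation, fatty acid oxidation, proximal tubule, other kidney segments, hepatocytes, bile acids and sterols, germ cells in meiosis, spermatids, Sertoli cells, steroidogenesis, granulosa cells, oocytes, erythroid cells, immune cells, endothelium, skeletal muscle, smooth muscle and fibroblasts, immediate early genes, heat shock, ribosomal proteins, rat liver P450 enzymes and partners of males and of females, the acute phase, and sex hormone receptors. Lists with at least 4 measured members were tested with limma's camera at its preset correlation of 0.01, adjusted over lists and contrasts of a species. Members are counted by the adjusted p over all genes tested, and the count adjusted over the list alone was equal to it for every list in the report except where it is given. Of 163 such tests, 67 passed at the preset correlation and 0 with a correlation estimated from the residuals, where the lowest adjusted p was 0.278. The estimated mode rests on the 2 residual degrees of freedom of the fit, so hardly any list could pass in it. For cardiac muscle in marmoset heart the estimated correlation was -0.029, below the preset one, and the camera adjusted p was still 0.439. A high adjusted p in that mode is therefore no evidence of correlation within a list. For untested comparisons, a list's median difference is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. Such a percentile describes these libraries and is not a test. XIST and RSX matched no entry of the tables used and were not analysed here.

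Genes are named by a rule fixed in advance, for genes with a symbol. From each limma contrast come the 5 with the largest rise (in testis also the 5 with the largest fall) among those whose lowest library of the tissue lies above the highest of every other tissue, plus 2 to 6 members of the lists of that tissue. From an untested tissue come the 10 with the largest gap to the other libraries. From the sexes come up to 10 genes per direction over all tissues, and in liver and kidney up to 5 per direction with at least 5 FPKM in the higher. Every Y-linked gene and X partner could be named, as could other list members as examples. A few genes that the rule selects are not reported here. Entries for which DDX3X or another symbol occurs more than once are reported by entry. Genes with close copies, such as those of the cytochrome P450, Mup and protamine families, may share fragments, and how these were assigned is not given in the sources used here.

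The limma and counting steps were tested on simulated data with 200 changed genes per comparison. Of genes changed by a log2 of 2, limma recovered between 95.5% and 100% in the somatic contrasts and 73.1% in marmoset testis. The alternatives tried were a pseudocount of 0.1, other filters on low values, rescaling of the libraries by median ratios, limma without a trend, no animal block, each library left out in turn, and an estimated correlation in the list tests. Chosen after seeing the data were the results without mitochondrial and Y-linked genes and those without the library labelled male kidney or both kidney libraries of the marmoset. So were the testis filter at 2 libraries, the list tests after rescaling, and the marmoset testis count by gaps. Rescaling moved the median log2 change of all tested genes by -0.16 in marmoset liver, 0.28 in marmoset testis, 0.14 in rat kidney and -0.13 in rat liver. For those contrasts, list medians are given relative to the median of all genes. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.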

Results

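Expression was measured by sequencing of polyadenylated RNA in tissues of males and females, in a series on the Y chromosome genes that mammals have kept and on where these genes are expressed. The libraries compared were heart, kidney and liver of 1 male and 1 female, testis and ovary in the marmoset and the rat, and liver and testis of a male wallaby. The marmoset testis values are the authors' own value for 3 samples of 2 individuals. Summed FPKM per library ranged from 258280 (marmoset ovary) to 1686921 (male marmoset liver) in the marmoset, from 457975 (rat ovary) to 3551202 (male rat heart) in the rat, and was 1757218 in wallaby liver and 453380 in wallaby testis. Between 9305 genes (wallaby testis) and 12932 genes (male marmoset kidney) reached 1 FPKM. Mitochondrial genes held 78.3% and 82.1% of the summed FPKM in the male and female rat heart, although MTCO3, MT-ATP6, ATP8 and COX1, mitochondrial genes at 52531 FPKM or more in both rat livers, were listed at 0 in both hearts. These sums reflect the authors' normalization and not the sequencing depth, which is unknown.

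The first question was where Y-linked genes are expressed. In the marmoset 29 genes were marked as Y-linked, of which 19 were restricted to testis and 10 were expressed more broadly. Restriction rests on values of 0 or near 0 elsewhere, and 4 of the 19, all CDY pseudogenes, were close to 0 in testis as well, 3 of them at 0.000266 FPKM or less. Of the 15 with at least 5 FPKM in a library, 10 were restricted. In the rat 6 of 12 were restricted to testis, 5 were broad, and SRY, the testis-determining gene, was listed at 0 in every library. All female libraries were listed at exactly 0 for every Y-linked gene in both species. How female reads were treated for these genes is not given in the sources used here, so these zeros are not a measured background. Each value is a single library or, for marmoset testis, the authors' value, so no error can be given.

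The 10 broad marmoset entries included 2 noncoding entries and 2 pseudogenes besides protein-coding genes. DDX3Y, an RNA helicase, stood at 15.8 FPKM in male marmoset heart, 9.49 FPKM in liver and 22.6 FPKM in testis, and at 19.5, 15.8 and 5.60 FPKM in the same rat tissues. ZFY, a zinc finger transcription factor, stood at 6.71 FPKM in marmoset heart and 8.03 FPKM in liver against 2.57 FPKM in testis. KDM5D, a histone H3 lysine demethylase, stood at 6.25, 7.32 and 8.66 FPKM in marmoset heart, liver and testis, and UTY, the Y-linked relative of the demethylase KDM6A, at 3.66, 3.85 and 0.830 FPKM. In the rat, EIF2S3Y, a subunit of a translation initiation factor, was the highest Y-linked gene in heart (39.1 FPKM), kidney (27.6 FPKM) and liver (30.4 FPKM) and stood at 14.8 FPKM in testis. Rat UTY, KDM5D and the entry named Med14X, marked as Y-linked, were each at 0.723 FPKM or more in every male tissue, with UTY at 2.96 FPKM and KDM5D at 2.21 FPKM in kidney. USP9Y, a deubiquitinase, differed in pattern: at most 0.333 FPKM in any marmoset tissue, and in the rat 6.23 FPKM in testis and 0 in heart, kidney and liver. XG stood at 3.08 FPKM in marmoset heart and 3.93 FPKM in testis, and a pseudogene marked XGPY reached 63.3 FPKM in heart.

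Testis-restricted Y-linked genes in the marmoset were led by RBMY, an RNA-binding protein gene of germ cells (33.1 FPKM), and TSPY, a gene of spermatogonia (31.3 FPKM), both listed at 0 in heart, kidney and liver. EIF1AY, a translation initiation factor, stood at 15.4 FPKM in marmoset testis, which was 96.3% of its summed male level. CDY1, a chromodomain gene, was at 1.13 FPKM and SRY at 0.214 FPKM. Of the 10 noncoding Y-linked entries, 8 were listed above 0 in testis alone, and the highest of these was at 14.9 FPKM. In rat testis the highest were Ssty1, a spermiogenesis gene (29.9 FPKM), and UBE1Y1, a ubiquitin-activating enzyme (23.1 FPKM, 98.5% of its male sum). Rat RBMY stood at 4.11 FPKM, ZFY1 at 0.687 FPKM and ZFY2 at 0.441 FPKM in testis.

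The marmoset library labelled male kidney stood apart. Of the 11 Y-linked genes above 0 in both heart and liver, 6 were listed at 0 in it, among them UTY, EIF1AY, USP9Y and XG. KDM5D was at 0.00789 FPKM and ZFY at 0.383 FPKM there. DDX3Y, at 4.71 FPKM, kept the highest ratio to the mean of heart and liver, 0.372. In the male rat kidney the level was between 55.0% (DDX3Y) and 149.7% (Med14X) of the mean of heart and liver over the 5 genes chosen in the same way, with a median ratio of 0.788.

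**Figure D1:**
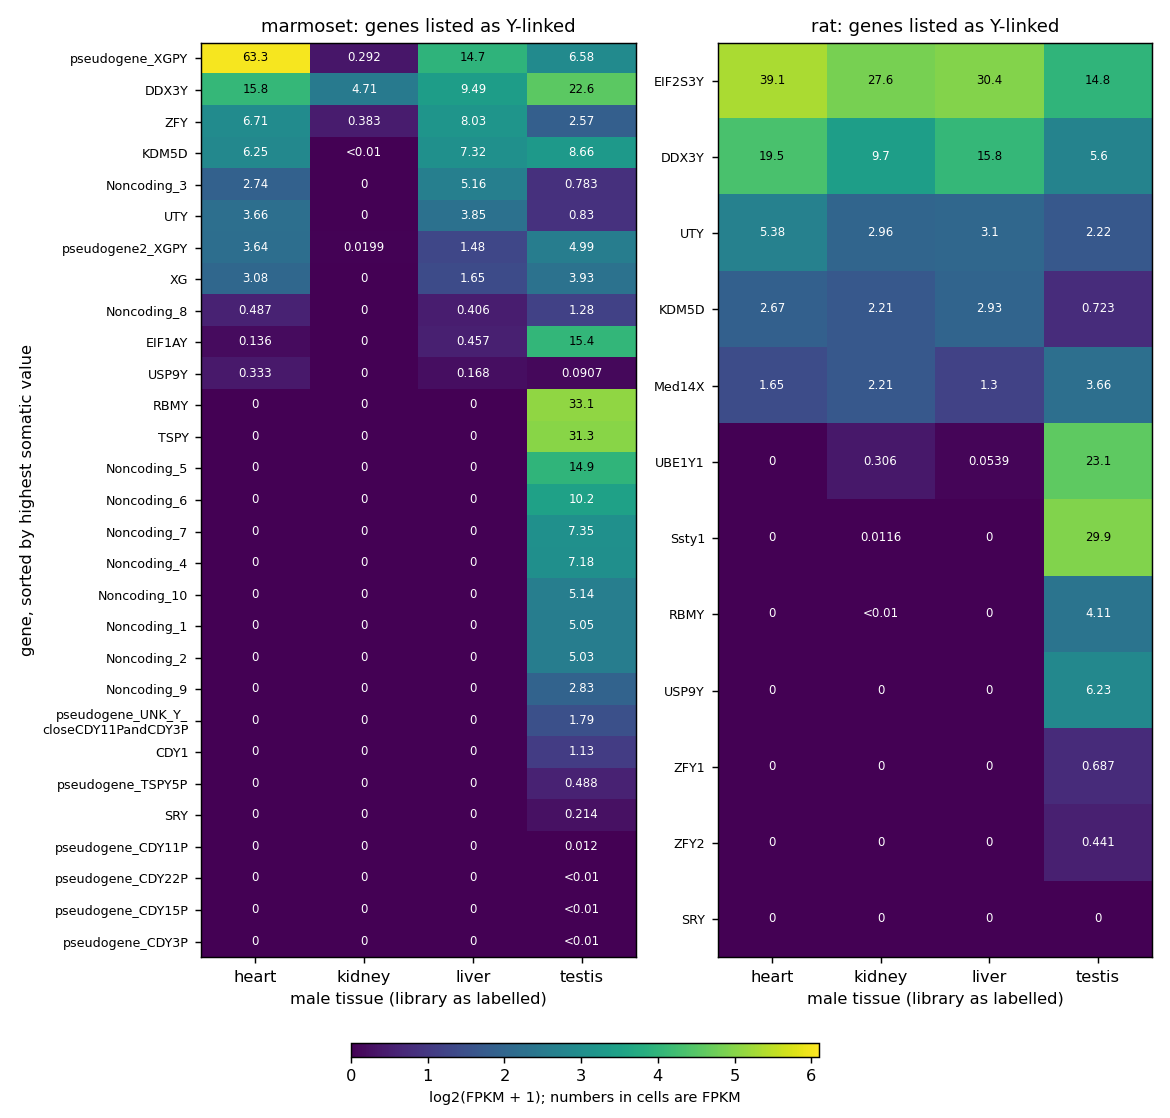
FPKM of the 29 marmoset and 12 rat Y-linked genes in male heart, kidney, liver and testis, with the value in each cell and colour as log2(FPKM + 1). DDX3Y is above 0 in every male tissue of both species, RBMY and TSPY are above 0 in marmoset testis alone (33.1 and 31.3 FPKM), and 6 of the 11 marmoset genes above 0 in both heart and liver are at 0 in the library labelled male kidney.

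X partners are the X-linked relatives of Y-linked genes, and their level in females bears on whether 2 X copies stay active. The median female minus male difference of the list was 0.34 log2 in heart, 0.26 in kidney and 0.54 in liver over 18 marmoset genes, with 12, 12 and 13 of them higher in the female. In the rat it was 0.34, 0.39 and 0.38 over 21 genes, with 15, 15 and 20 higher in the female, or 0.38, 0.62 and 0.52 with 15, 18 and 20 higher after rescaling. The male minus female medians, the same values with the opposite sign, lay at percentile 0.67, 0.70 and 0.04 of matched random lists in the marmoset and 0.31, 0.01 and 0.04 in the rat. All 450 X-linked genes of the marmoset had male minus female medians of 0.18, 0.06 and 0.05, and the 371 of the rat -0.06, -0.04 and -0.03. With 1 animal per sex there is no replicate check. A check of gene length in the marmoset was scored as void, since 67.8% of the genes that differed matched a gene model. Among the matched genes, which differed in heart, kidney and liver after rescaling, 96.3% were male-higher in the shortest group by span. In the longest group 31.0% were male-higher, so most of the longest were female-higher. The random lists were matched on mean expression and not on gene length. No check of length was made in the rat. An effect of gene length on these ratios and percentiles therefore stays open. The marmoset kidney values rest on the library labelled male kidney, which had little Y-linked expression.

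Female excess was found in partners with and without a Y-linked relative in the table, and the groups were not tested against each other. KDM6A, a histone demethylase, was 1.86, 1.42 and 2.29 times as high in the female as in the male marmoset in heart, kidney and liver, and 2.02, 2.27 and 1.91 times in the rat. USP9X was 2.42, 1.68 and 2.19 times as high in the female marmoset, ZFX 2.41, 1.33 and 2.22 times and DDX3X 1.31, 1.23 and 1.51 times. Rat Ddx3x was 2.35, 1.71 and 1.55 times as high in the female, Kdm5c 2.66, 2.32 and 1.55 times and Eif2s3 1.98, 1.42 and 1.33 times. ATRX, a chromatin remodeller with no Y-linked relative in the tables, was 2.91, 4.75 and 7.49 times as high in the female marmoset and 2.57, 6.07 and 3.38 times in the female rat. Its male levels were low, at 2.21, 0.395 and 0.152 FPKM in the marmoset and 0.483, 0.419 and 0.230 FPKM in the rat. Ratios to values this near 0 are uncertain. HUWE1, a ubiquitin ligase with no Y-linked relative in the tables either, was 2.23, 2.04 and 1.69 times as high in the female marmoset and 2.31, 2.44 and 1.51 times in the female rat. Some members went the other way: marmoset RPL10, a ribosomal protein gene, had female over male ratios of 0.292, 0.580 and 0.277, RBM10 of 0.387, 0.410 and 0.360, and rat Zfx of 0.874, 0.699 and 0.586. The summed male X and Y level of KDM6A with UTY was 0.923, 0.705 and 0.852 of the female X level in the marmoset, where UTY was listed at 0 in the library labelled male kidney, and 1.14, 0.784 and 0.843 in the rat. For EIF2S3 with EIF2S3Y the rat ratio was 1.42, 1.45 and 1.77. Other pairs varied. In the marmoset the ratio was 0.425, 0.594 and 0.463 for USP9X, 1.13, 0.807 and 1.72 for ZFX and 1.72, 1.01 and 0.881 for TSPYL2. In the rat it was 0.513, 0.411 and 0.613 for Rbmx and 1.15, 1.43 and 1.13 for Med14. Marmoset DDX3X and rat Ddx3x, Usp9x, Kdm5c and Uba1 stayed below the female X level in each tissue, and rat Zfx above it. Marmoset TSPY and rat USP9Y, ZFY1 and ZFY2 were listed at 0 in these tissues. Rescaling of the libraries widened the marmoset medians to 0.76, 0.52 and 0.72, with 13, 14 and 14 higher in the female.

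**Figure D2:**
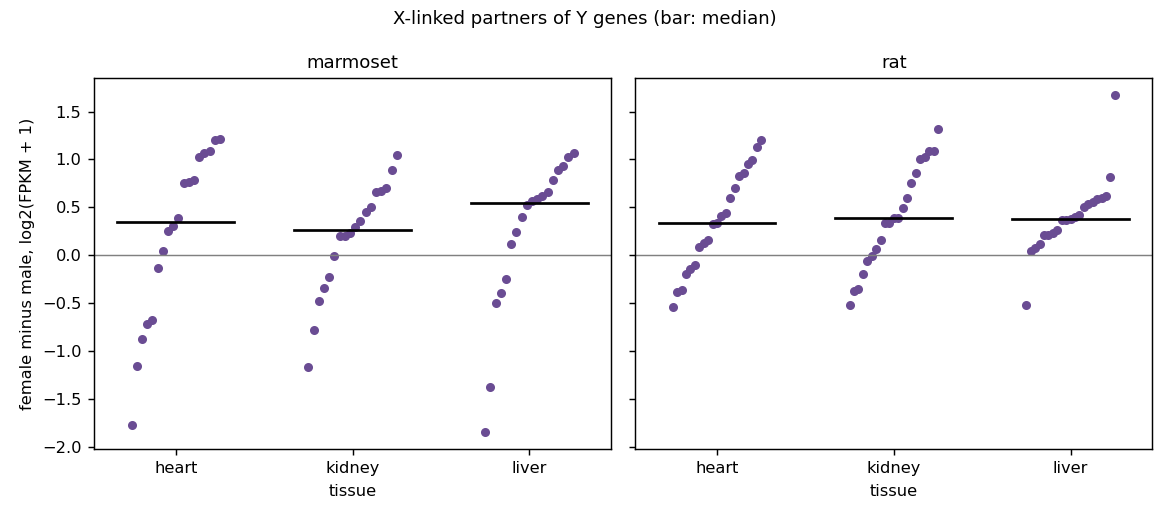
Female minus male log2(FPKM + 1) of each X partner in heart, kidney and liver, 18 genes in the marmoset and 21 in the rat, with 1 point per gene and a bar at the median. The medians lie between 0.26 and 0.54 in the marmoset and between 0.34 and 0.39 in the rat.

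Tissue differences in heart, kidney and liver were tested next, since they set the background against which Y-linked and sex-biased expression is read. Marmoset heart was led by contractile genes together with the gene of myoglobin. ACTC1, cardiac actin, was higher than in the mean of kidney and liver by 10.89 ± 0.21 log2 (limma estimate ± SE, adjusted p = 6.56e-05), at 3724 ± 917 FPKM (SD, n = 2), and MB, myoglobin, by 10.55 ± 0.35 (adjusted p = 8.84e-05), at 5636 ± 2182 FPKM. ACTA1, skeletal actin, MYL6, a myosin light chain, and HSPB7, a small heat shock protein of muscle, were higher by 10.67, 10.40 and 10.17. By limma, 1940 of 13967 genes were higher and 3163 lower in heart.

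Of the 13 measured cardiac muscle genes 12 rose, with a median of 7.95 log2 (camera adjusted p = 7.00e-10; adjusted p = 0.439 with an estimated correlation). Examples were CSRP3, a Z-disc protein, by 9.43 ± 0.18 (limma adjusted p = 6.56e-05), TNNC1, troponin C, by 8.99, and MYBPC3, myosin-binding protein C, by 8.98. MYH7, a myosin heavy chain of the list, was listed at 0 in the male heart, which can be a failed estimate, and stood at 1044 FPKM in the female heart. Oxidative phosphorylation rose in 11 of 15 genes with a median of 1.59 (adjusted p = 4.61e-06; 0.439 as the adjusted p with an estimated correlation), among them COX7A1 by 2.68 ± 0.29, a cytochrome c oxidase subunit of muscle, and NDUFS1, of complex I, by 2.28 ± 0.25. COX7A1, ATP5B and UQCRFS1 no longer passed without the animal block, where limma gave adjusted p of 0.332, 0.114 and 0.311. In fatty acid oxidation 5 of 10 genes were higher and 2 lower, and the list did not pass (adjusted p = 0.0715). The fatty acid transporter CD36 rose by 4.06 ± 0.28 and the muscle isoform CPT1B of the carnitine transferase by 3.73 ± 0.21, while its liver isoform CPT1A fell by 3.37. HADHB, HADHA and ACAA2, enzymes of beta-oxidation, were at 1.56, 1.15 and -1.29. All 3 lost their limma call without the animal block (adjusted p = 0.0607, 0.0817 and 0.0815, the highest of their alternatives) and without the female heart library, and HADHB also without the male heart library. Smooth muscle and fibroblast genes rose in 6 of 8 (adjusted p = 7.22e-04; adjusted p = 0.466 with an estimated correlation) and endothelial genes in 4 of 6 (adjusted p = 0.00276; 0.539 as the adjusted p with an estimated correlation), while 7 of 7 immune genes fell (adjusted p = 0.00161; 0.466 with an estimated correlation). Without the animal block 2975 genes passed in place of 5103.

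Rat heart was also led by contractile genes. Myl2, the ventricular myosin light chain, was higher by 12.77 ± 0.55 log2 (limma adjusted p = 3.35e-05), Actc1 by 12.51 ± 0.36, and Pln, phospholamban, a regulator of calcium uptake, by 11.16 ± 0.24 (adjusted p = 1.10e-05). Mb was higher by 12.06 ± 0.43, and Myl3, another myosin light chain, by 11.05 ± 0.20. All 17 cardiac muscle genes rose, with a median of 8.88 (camera adjusted p = 8.60e-13; adjusted p = 0.278 with an estimated correlation), including Tnni3, troponin I, at 2033 ± 101 FPKM (SD, n = 2) and higher by 10.10 ± 0.20. All 17 oxidative phosphorylation genes rose, with a median of 2.10 (adjusted p = 2.96e-06; adjusted p = 0.686 with an estimated correlation). They included Uqcrc2 by 3.23 ± 0.28, Ndufs1 by 2.80 ± 0.27, Ndufv1 by 2.45 ± 0.29 and Cox5a by 2.34 ± 0.47. Cyc1, cytochrome c1, rose by 2.18 ± 0.30 (limma adjusted p = 0.00198) and did not pass without the animal block (adjusted p = 0.0577). In fatty acid oxidation 10 of 12 rose and 1 fell (median 2.12, adjusted p = 5.20e-04; adjusted p = 0.634 with an estimated correlation), with Fabp3, the heart fatty acid binding protein, higher by 7.42 ± 0.23 at 5938 ± 65.8 FPKM, Cpt1b by 6.19 ± 0.22, Cd36 by 5.09 ± 0.78 and Acadl by 3.02 ± 0.25. Endothelial genes rose in 7 of 8 (adjusted p = 8.71e-04; 0.401 with an estimated correlation) and smooth muscle and fibroblast genes in 5 of 7 (adjusted p = 0.00292; 0.677 with an estimated correlation). By limma, 2343 of 13128 genes were higher and 2642 lower.

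Marmoset kidney was led by genes of the nephron segments. SLC34A1, the phosphate transporter of the proximal tubule, was higher by 9.96 ± 0.40 log2 (limma adjusted p = 2.93e-04), UMOD, uromodulin of the thick ascending limb, by 8.72 ± 0.43 (adjusted p = 3.87e-04), and KLK1, tissue kallikrein, by 9.57 ± 0.36 (adjusted p = 2.64e-04). TSPAN1 was higher by 9.00 ± 0.27 at 834 ± 292 FPKM (SD, n = 2) and C8orf22 by 8.72 ± 1.39. All 13 proximal tubule genes rose, with a median of 5.78 (camera adjusted p = 2.45e-11; adjusted p = 0.476 with an estimated correlation). Among them were SLC22A2 and SLC22A6, transporters of organic ions, by 7.90 and 7.66, CUBN, cubilin, an endocytic receptor, by 7.79 ± 0.30 at 397 ± 13.3 FPKM, and SLC5A2, the glucose transporter, by 6.82 ± 0.45. Genes of other kidney segments rose in 13 of 14, with a median of 6.04 (adjusted p = 8.65e-12; adjusted p = 0.539 with an estimated correlation). Examples were CDH16, kidney cadherin, by 8.66 ± 0.25, CALB1, a calcium-binding protein of the distal tubule, by 7.72 ± 0.20, and AQP2, the water channel of the collecting duct, by 7.07 ± 0.39. Immune genes rose in 7 of 7, with a median of 2.09 (adjusted p = 9.04e-05; adjusted p = 0.461 with an estimated correlation), and 10 of 15 oxidative phosphorylation genes fell, with a median of -1.16 (adjusted p = 1.64e-05; 0.439 with an estimated correlation).

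By limma, 1800 marmoset genes were higher and 1482 lower in kidney, 3282 in all. The total was 1719 without the animal block, 1378 without the library labelled male kidney, which had little Y-linked expression, and 1506 without the female kidney library.

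Rat kidney was led by Kap, the androgen-regulated protein of the proximal tubule, higher by 12.40 ± 0.84 log2 (limma adjusted p = 2.05e-04), Defb1, a defensin, by 11.00 ± 0.81, and Umod by 9.93 ± 0.20 (adjusted p = 3.10e-05), at 1368 ± 419 FPKM (SD, n = 2). Dnase1 was higher by 9.73 ± 0.46. Tmem213 was at 2108 ± 2259 FPKM in kidney and listed at 0 in all heart and liver libraries. Proximal tubule genes rose in 12 of 13, with a median of 5.34 relative to all genes (camera adjusted p = 3.91e-09; adjusted p = 0.364 with an estimated correlation), including Slc34a1 by 9.39 ± 0.61, Slc3a1, a transporter of cystine, by 9.32 ± 0.21, Miox, the inositol oxygenase, by 9.15 ± 0.75, Ggt1 by 8.63 ± 0.38 and Slc22a6 by 6.83 ± 0.36. All 16 genes of other segments rose, with a relative median of 6.40 (adjusted p = 9.72e-15; adjusted p = 0.278 with an estimated correlation), among them Calb1 by 8.02 ± 0.24, and Slc12a1 and Slc12a3, salt transporters of the ascending limb and the distal tubule, by 7.34 ± 0.30 and 7.28 ± 0.21. Fatty acid oxidation fell in 10 of 12 genes (relative median -1.91, adjusted p = 0.00194; adjusted p = 0.677 with an estimated correlation), and oxidative phosphorylation in 9 of 17, or 11 adjusted over the list alone (relative median -0.98, adjusted p = 7.27e-04; 0.825 with an estimated correlation). By limma, 1673 genes were higher and 1751 lower, or 1916 and 1471 after rescaling.

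Marmoset liver was led by genes of secreted plasma proteins. APOC3, an apolipoprotein, was higher by 12.07 ± 0.65 log2 (limma adjusted p = 1.93e-04), AHSG, fetuin A, by 11.99 ± 0.43 (adjusted p = 6.84e-05), and HPX, hemopexin, by 11.28 ± 0.45. CYP2E1, a P450 enzyme, was higher by 11.22 ± 0.49 at 5526 ± 1282 FPKM (SD, n = 2), and FOLR3 by 11.10 ± 0.46. Of 18 hepatocyte genes 13 rose and 1 was counted as lower, with a median of 8.65 relative to all genes (camera adjusted p = 3.52e-07; adjusted p = 0.539 with an estimated correlation). They included CPS1, of the urea cycle, by 10.21 ± 0.30, TAT, tyrosine aminotransferase, by 10.19 ± 0.41, and F2, prothrombin, by 9.52 ± 0.20 (limma adjusted p = 4.81e-05). The gene counted as lower was ALB, listed at 0 in both liver libraries, and FGA, FGB, FGG and SERPINA1, which did not pass, were listed at 0 in the male liver. All 13 bile acid and sterol genes rose (relative median 4.92, adjusted p = 5.47e-08; adjusted p = 0.439 with an estimated correlation), among them NR0B2, a nuclear receptor that represses bile acid synthesis, by 6.74 ± 0.29, BAAT, which conjugates bile acids, by 6.25 ± 0.22, CYP8B1 by 5.26 ± 0.47, CYP27A1 by 5.11 ± 0.24, and ABCB11, the bile salt export pump, by 4.99 ± 0.24. SLC10A1, the bile acid uptake transporter, was at 88.7 ± 8.76 FPKM and listed at 0 in heart and kidney. Acute phase genes rose in 5 of 6 (relative median 7.86, adjusted p = 0.00328; adjusted p = 0.539 with an estimated correlation), with CRP higher by 8.15 ± 0.26 and SAA4 by 9.23 ± 0.58. By limma, 2504 genes were higher and 2003 lower, or 2100 and 2341 after rescaling. Without the animal block the total of 4507 was 2494.

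Rat liver was led by Apoa2, an apolipoprotein of high-density lipoprotein, higher by 12.37 ± 0.26 log2 (limma adjusted p = 5.26e-06) at 8655 ± 3484 FPKM (SD, n = 2), Serpina1, alpha-1-antitrypsin, by 12.35 ± 0.27, Hp, haptoglobin, by 12.11 ± 0.29, Ahsg by 12.09 ± 0.37 and Apoc1 by 11.89 ± 0.37. Hepatocyte genes rose in 19 of 20, with a median of 10.04 relative to all genes (camera adjusted p = 1.06e-12; adjusted p = 0.304 with an estimated correlation). The other, Alb, was counted as lower because it was listed at 0 in both liver libraries. Bile acid and sterol genes rose in 12 of 13 (relative median 4.21, adjusted p = 1.27e-08; adjusted p = 0.278 with an estimated correlation). Among these, Slc10a1 was higher by 9.27 ± 0.23, Cyp8b1 by 8.75 ± 0.20, Baat by 8.23 ± 0.18, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 6.28 ± 0.24 at 81.6 ± 29.0 FPKM. Acute phase genes rose in 5 of 6 (relative median 10.58, adjusted p = 8.71e-04; adjusted p = 0.401 with an estimated correlation), including Crp by 11.66 ± 0.33, Orm1 by 11.02 ± 0.35 and Hamp, hepcidin, by 10.13 ± 0.42. Ribosomal protein genes rose in 4 of 18 (adjusted p = 0.0376; adjusted p = 0.686 with an estimated correlation). By limma, 2337 genes were higher and 2344 lower.

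**Figure D3:**
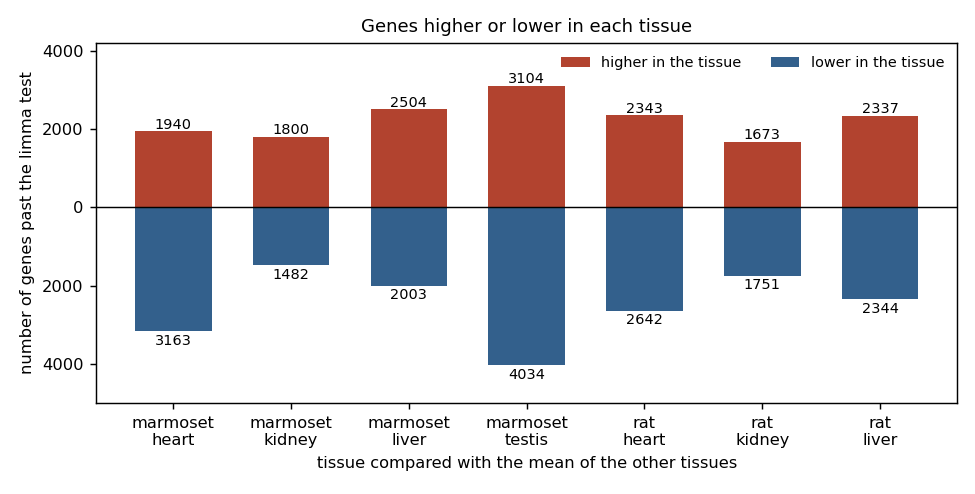
Number of genes past the limma threshold in each of 7 contrasts, higher in the tissue above the zero line and lower below it. The totals run from 3282 in marmoset kidney (1800 higher and 1482 lower) to 7138 in marmoset testis (3104 higher and 4034 lower).

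Markers of cells not sampled on purpose were measured in the same contrasts. Erythroid genes did not pass camera in heart of either species (adjusted p = 0.370 in the marmoset, 0.584 in the rat), nor did astrocyte genes (0.336 and 0.549) and cortical neuron genes (0.969 and 0.266). Myelin genes, measured in the rat, had an adjusted p of 0.940 in heart, 0.810 in kidney and 0.649 in liver, and synapse genes, measured in the marmoset, 0.501 in heart. Skeletal muscle genes in marmoset heart, with 3 higher and 1 lower of 5, had an adjusted p of 0.0604. Of this list, MYH4 was listed at 0 in the male heart and stood at 1179 FPKM in the female heart. Immediate early genes, which respond within minutes to stimuli, had 0.191 and 0.549 in heart. Rat P450 genes of females rose in liver in 4 of 6 (camera adjusted p = 0.0114; adjusted p = 0.825 with an estimated correlation), and those of males in 2 of 5, or 3 adjusted over the list alone, without passing as a list (adjusted p = 0.144).

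Testis was compared with the somatic tissues in 3 species. The marmoset testis p-values come from a single column, assumed to vary like the somatic libraries, and hold only as far as that does. In marmoset testis the gene with the highest level was SCGB1D1, a secretoglobin, at 7143 FPKM and listed at 0 in all other libraries (limma adjusted p = 0.00125). FATE1, an X-linked testis gene, was higher by 8.45 log2 (adjusted p = 0.00248), DEFB129, a beta-defensin, by 8.26, OBP2A, an odorant-binding lipocalin, by 7.96, and VSIG1, X-linked, by 7.85. RBP5, a retinol-binding protein, was at -7.66 (adjusted p = 0.00163), MPC1, of the mitochondrial pyruvate carrier, at -7.41, PON1 at -7.18 and HPN at -6.97. DEFB1 was at -7.46 (adjusted p = 0.0106) and no longer passed without the library labelled male kidney or without both kidney libraries, its highest adjusted p over all alternatives being 0.0793.

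Genes of germ cells in meiosis rose in 7 of 9 in marmoset testis, with a median of 3.17 relative to all genes (camera adjusted p = 2.26e-05; adjusted p = 0.466 with an estimated correlation). They included DDX4, a germ cell helicase, by 4.92 (limma adjusted p = 0.00125) at 29.8 FPKM, SMC1B, a meiotic cohesin, by 3.95, SYCP1, of the synaptonemal complex, by 3.64, and MAEL and PIWIL1, of the piRNA pathway, by 3.16 and 2.88. DDX4 was listed at 0 in 5 of the 6 somatic libraries, as was HSD17B3. Steroidogenic genes rose in 5 of 6 (relative median 4.32, adjusted p = 0.00296; adjusted p = 0.539 with an estimated correlation), among them CYP17A1 by 6.58 at 277 FPKM, HSD17B3, which makes testosterone, by 6.48, and STAR, the cholesterol carrier, by 4.19. CYP11A1 was at 1.91 (limma adjusted p = 0.0350) and lost its call with a pseudocount of 0.1, with no filter, without the sex block, and without any 1 library other than the female liver, with adjusted p up to 0.107. Sertoli cell genes were higher in 4 of 7 (relative median 2.72) without passing as a list (adjusted p = 0.0604), and these were SOX9 by 3.56, WT1 by 2.60, AMH, anti-Mullerian hormone, by 2.55, and DHH by 2.43. Spermatid genes were higher in 1 of 4, LDHC, the sperm lactate dehydrogenase, by 1.00 at 1.89 FPKM, and did not pass as a list (adjusted p = 0.607). LDHC lost its limma call without either heart library, without either kidney library and without both kidney libraries, with adjusted p up to 0.0838. Y-linked genes rose in 3 of 7 (relative median 1.59, adjusted p = 0.0274; adjusted p = 0.601 with an estimated correlation), and X partners were higher in 8 and lower in 2 of 19 (adjusted p = 0.0604). All 15 oxidative phosphorylation genes fell (relative median -2.54, adjusted p = 2.39e-05; 0.439 with an estimated correlation), as did 6 of 6 endothelial genes (adjusted p = 0.0344; 0.539 with an estimated correlation). By limma, 3104 of 15657 genes were higher and 4034 lower, or 3907 and 3236 after rescaling. The total of 7138 was 3611 without the sex block and 4367 without the library labelled male kidney.

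The genes that stood highest above the other tissues in rat testis included many of spermatids. Oaz3, the testis antizyme, was at 9442 FPKM and above every heart, kidney and liver library by at least 10.57 log2, Odf1, of the outer dense fibres of the sperm tail, at 3717 FPKM, and Prm1 and Tnp2, the protamine and transition protein that replace histones, at 5435 and 4016 FPKM. Smcp, of the sperm mitochondrial capsule, stood at 5555 FPKM, Cox8c at 2051 FPKM, Fabp9 at 1929.7 FPKM, Hspb9 at 1921 FPKM, Rpl39l at 1646 FPKM and Spink2 at 1274 FPKM. The spermatid list had a median testis minus somatic difference of 8.57 over 17 genes, above all 10000 matched random lists, with all 17 higher by at least 1. The meiosis list had a median of 4.62 over 14 genes (percentile 100), led by Mael at 9.33 and Sycp3 at 7.05, and the steroidogenic list 2.55 over 9 genes (percentile 99.9), led by Insl3, the Leydig cell hormone, at 6.89. Sertoli genes had a median of 1.10 (percentile 83.7), with Cldn11, of the blood-testis barrier, at 5.05. Lower in testis than in every somatic library were Cox7b, an X-linked cytochrome oxidase subunit, by a gap of -5.72, Gstk1 by -5.06, Bckdhb by -4.93 and Cat, catalase, by -4.74. In all, 2293 genes lay above and 514 below every somatic library by at least 2 log2, or 2719 and 371 after rescaling and 3260 and 1080 with a pseudocount of 0.1. With 1 library there is no replicate check.

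In wallaby testis, PRM1 was at 72536 FPKM against 78.2 FPKM in liver, a difference of 9.84 log2, and TNP1 at 9476 FPKM against 13.9 FPKM, a difference of 9.31. ROPN1L, of the sperm flagellum, was higher by 9.29, SPATA19 by 9.11, and AKAP4, the X-linked anchor protein of the fibrous sheath, by 8.76. TXNDC8, ZC2HC1B and TRIQK were at 661, 625 and 368 FPKM in testis and listed at 0 in liver. The spermatid list had a median of 8.85 relative to all genes over 8 members, the meiosis list 5.22 over 10, the Sertoli list 2.66 over 8 and the steroidogenic list 2.87 over 6, at percentiles 100, 99.99, 98.7 and 99.4. Liver genes were lower in testis: APOC2 by -13.00, HAMP by -12.08, and the 16 hepatocyte genes with a relative median of -9.35 (percentile 0). X-linked genes, 110 in number, had a relative median of -1.13, below all matched random lists. Higher and lower genes numbered 1423 and 3229 of 8915, or 2118 and 2005 after rescaling. One library per tissue gives no replicate check.

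By the gap count used for the rat, 744 genes in marmoset testis lay above and 241 below every somatic library. These were 876 and 217 after rescaling and 1381 and 432 with a pseudocount of 0.1. The 744 genes above comprised 34.5% of Y-linked, 12.1% of X-linked and 3.39% of other marmoset genes, against 33.3%, 14.5% and 11.1% in the rat. This count was chosen after seeing the data. Marmoset genes with the largest gaps included PNMA5 (128 FPKM, gap 6.97), PVALB, parvalbumin (305 FPKM, gap 6.74), HSD17B3 (gap 6.38), LY6L (gap 6.38) and SSX4B, X-linked, at 91.6 FPKM and listed at 0 elsewhere.

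**Figure D4:**
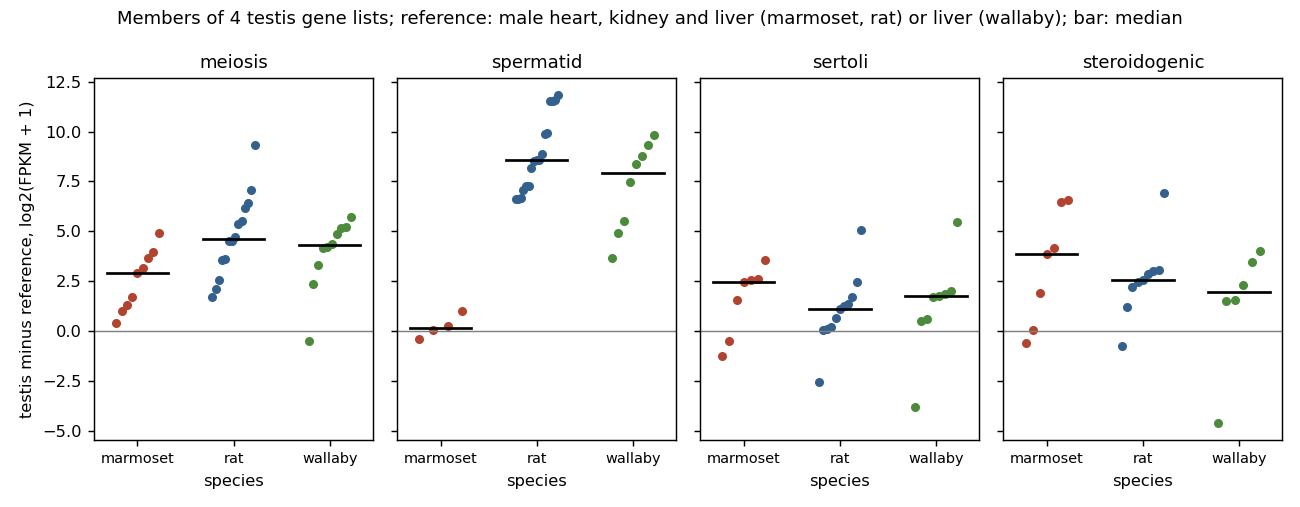
Testis minus mean of male heart, kidney and liver (in the wallaby, minus liver) in log2(FPKM + 1) for each member of the meiosis, spermatid, Sertoli and steroidogenic lists with at least 1 FPKM in a library, with a bar at the median. The spermatid medians are 0.13 over 4 genes in the marmoset, 8.57 over 17 in the rat and 7.92 over 8 in the wallaby, and the meiosis medians 2.88 over 9, 4.62 over 14 and 4.29 over 10, none of them relative to all genes.

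Ovary was set against the somatic tissues in the marmoset and the rat. In marmoset ovary ZP4, a protein of the egg coat, stood at 41.3 FPKM, 5.32 log2 above every heart, kidney and liver library, SPINK2 at 481 FPKM (gap 5.13), AMH at 23.8 FPKM (gap 4.40) and CYP17A1, the enzyme of androgen synthesis, at 122 FPKM (gap 4.15). MUM1L1 and NDP, both X-linked, had gaps of 4.17 and 4.05, PTTG1, securin, 4.13, STAR 4.05 and ZP3 3.99. The oocyte list had a median difference of 3.26 over 10 genes, all higher by at least 1, with FIGLA at 3.57 and GDF9 at 3.00. Granulosa genes had a median of 2.65 over 6, with FST, follistatin, at 3.83, and steroidogenic genes 3.35 over 7. All 3 medians lay above every matched random list. In all, 148 genes lay above and 80 below every somatic library, or 203 and 62 after rescaling and 464 and 181 with a pseudocount of 0.1.

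Rat ovary was led by genes of steroid synthesis. Cyp11a1, which makes pregnenolone, stood at 1451 FPKM with a gap of 7.79, Star at 459 FPKM (gap 8.05), and the 2 entries of Hsd3b1 at 628 and 329 FPKM (gaps 8.75 and 8.17). Lhcgr, the receptor of luteinizing hormone, stood at 79.1 FPKM (gap 5.94), Fabp6 at 214 FPKM, Pla2g1b at 166 FPKM, Kcne2 at 115 FPKM, Cuzd1 at 103 FPKM and Calb2 at 73.2 FPKM. The steroidogenic list had a median of 5.89 over 9 genes, the granulosa list 3.10 over 9, with Inha at 7.12 and Amh at 5.84, and the oocyte list 2.92 over 7, with Zp3 at 3.67, each above every matched random list. Smooth muscle and fibroblast genes were higher in both species, with medians of 3.03 (marmoset) and 2.67 (rat) over 8 genes each, led by COL1A1 at 3.77 in the marmoset and Lum at 4.48 in the rat. Genes above every somatic library numbered 149 and those below 38, or 184 and 31 after rescaling and 485 and 79 with a pseudocount of 0.1. Neither ovary has a replicate.

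The sexes were compared within heart, kidney and liver, with 1 animal per sex and no test. In rat liver P450 genes known to differ between the sexes were among those with the largest differences, together with genes listed at 0 in one sex. Cyp2c11, the male-specific testosterone hydroxylase, was at 2352 FPKM in the male and 0.445 FPKM in the female, a difference of 10.67 log2, and Cyp2c13 at 2780.1 against 0.960 FPKM (10.47). Cyp2c12, the female form, was at 3.73 FPKM in the male and 4922 FPKM in the female (-10.02). All 5 male P450 genes and partners were higher in the male, with a median of 7.67, including Cyp4a2 at 7.67 and Hsd3b5 at 7.68, and all 6 female ones were lower, with a median of -3.75, including Sult2a1 at -3.40 and Cux2, a female-specific repressor, at -4.10. These medians lay above and below all matched random lists. A1bg, Sult2a2 and Akr1b7 stood at 3367, 692 and 514 FPKM in the female and were listed at 0 in the male, and Mup5, a major urinary protein, was at 707 and 671 FPKM in its 2 entries in the male and at 0 in the female. Prlr, the prolactin receptor, was at 1.06 FPKM in the male and 179 FPKM in the female.

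Rat kidney also differed between the sexes. Dhrs7, a dehydrogenase, was at 277 FPKM in the male and 0.602 FPKM in the female (7.44 log2), Slc22a22 at 154 against 1.02 FPKM (6.26), Slc51b, an organic solute transporter, at 90.6 against 0.315 FPKM (6.12), and Akr1c12l1 at 134 against 1.05 FPKM (6.04). Cyp2c11 was at 115 FPKM in the male kidney and listed at 0 in the female. Higher in the female were Adh6 (89.0 against 1.08 FPKM, -5.44), Fabp4 (62.4 against 1.36 FPKM, -4.75), Car3 (79.2 against 3.22 FPKM, -4.25) and 1500009L16Rik (84.3 FPKM, listed at 0 in the male). Proximal tubule genes had a median of 1.09 relative to all genes over 13 members, above all matched random lists, with 8 higher by at least 1 in the male and 1 lower. Slc5a2 was at 4.66, Slc22a2 at 3.93, Miox at 2.22 and Cubn at -2.03. Erythroid genes had a median of -0.94 (percentile 0.07).

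**Figure D5:**
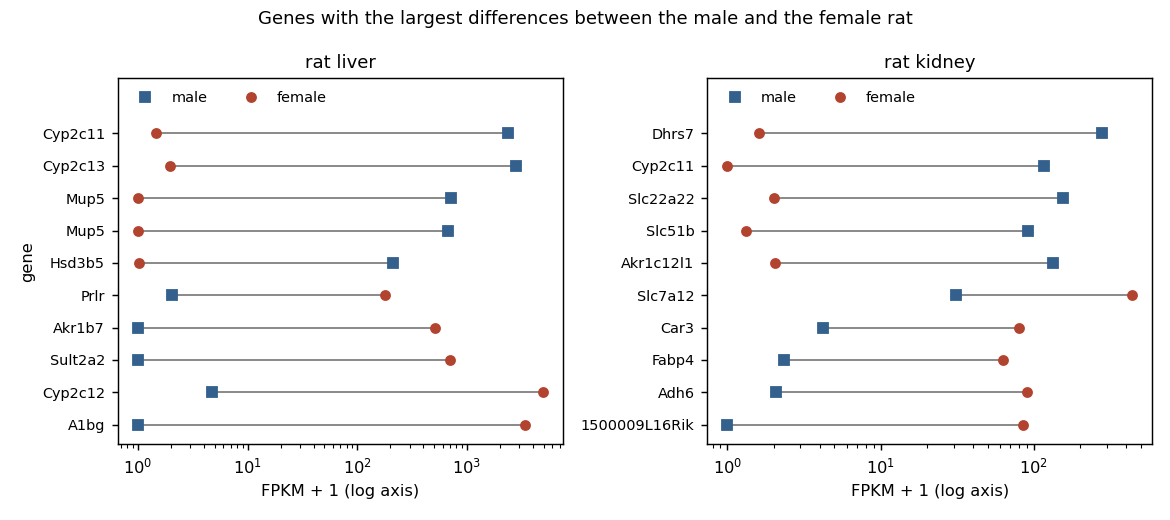
FPKM + 1 on a log axis in the male and female rat for the 5 genes with the largest difference in each direction in liver and in kidney, mitochondrial genes left out. Cyp2c11 is at 2352 FPKM in male and 0.445 FPKM in female liver, and Dhrs7 at 277 and 0.602 FPKM in kidney.

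Over all 3 rat tissues, 254 genes were higher in the male and 37 in the female by at least 1 log2 in each tissue, or 185 and 57 after rescaling and 401 and 163 with a pseudocount of 0.1. The total of 291 was 840 without heart and 504 without liver. With 1 male and 1 female, a library bias that follows a property of the gene cannot be told from a sex difference here. An effect of gene length was not checked in the rat. Besides EIF2S3Y and DDX3Y, the male-higher genes included Zfp771 (2.38, 3.78 and 3.44 in heart, kidney and liver), Cebpb, a transcription factor of the acute phase (2.29, 3.81 and 4.12), Mif, a cytokine (2.30, 3.23 and 2.55), Jund (2.30, 2.80 and 2.79) and the histone gene Hist2h2aa3 (2.44, 2.31 and 4.29). Female-higher genes included Ptma, prothymosin (-1.56, -1.83 and -1.69), and Npc2, a cholesterol transfer protein (-1.52, -1.76 and -1.65). In the male rat heart hepatocyte genes had a median of 0.84, above all matched random lists, and acute phase genes of 1.11 (percentile 99.99). Their levels were far below those of liver: Ahsg was at 8.91 FPKM in the male heart and 12457 FPKM in the male liver, and Apoa2 at 2.49 and 11119 FPKM. Where these heart transcripts came from was not tested. In male rat liver, immediate early genes had a median of 1.46 over 8 members, above all matched random lists, with Junb at 4.44 and Dusp1 at 3.41.

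In the marmoset, 1450 genes were higher in the male and 89 in the female in each of the 3 tissues, or 885 and 312 after rescaling. The total of 1539 was 2334 without kidney. The median male minus female difference of genes at 1 FPKM or more was 0.28 in heart, 0.20 in kidney and 0.16 in liver. ATP5F1D, a subunit of ATP synthase, was at 1100.1 against 22.6 FPKM in heart, 924 against 29.3 FPKM in kidney and 1012 against 44.3 FPKM in liver. CHCHD10, a mitochondrial protein, was higher in the male by 4.10, 3.18 and 3.13, COX7A1 by 3.69, 3.54 and 3.59, and ZNF865 by 3.56, 3.74 and 3.42. CFD, the complement factor D, was at 73.2, 145 and 169 FPKM in the male and 1.28, 6.15 and 12.1 FPKM in the female. Higher in the female were SH3BGRL, X-linked (-1.90, -1.83 and -2.13), ESF1 (-2.23, -1.64 and -1.85), PTMA (-1.78, -1.58 and -1.49) and ANP32A, a histone chaperone (-2.27, -1.48 and -1.79). Ribosomal protein genes had male minus female medians of 1.65, 1.01 and 1.69 relative to all genes over 13 members (percentiles 98.9, 97.9 and 99.8), with RPL13 at 3.89, 1.75 and 3.52. Among the genes that differed in all 3 tissues after rescaling and matched a gene model, the male-higher share fell with gene span. It was 96.3% in the shortest and 31.0% in the longest of 3 equal groups. An effect of gene length on the differences between the male and the female marmoset therefore stays open.

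In marmoset liver, PADI3 (61.5 against 0.0933 FPKM), NOTUM, a Wnt inhibitor (228 against 3.12 FPKM), SLC13A5, a citrate transporter (125 against 1.30 FPKM), MAPK13 (86.3 against 0.649 FPKM) and TAGLN3 (78.6 against 0.655 FPKM) had the largest male excess, while the genes with the largest female excess, HP, SERPINA1, FGG, FGB and FGA, were those listed at 0 in the male. Acute phase genes had a median of 2.60 in liver, above all matched random lists, with SAA1 at 5.56. Transcripts of the hepatocyte list were also higher in the male heart, with a relative median of 1.59 (14 of 18 by at least 1, above all matched random lists) and in the library labelled male kidney, with 0.88 (percentile 99.8). FGG stood at 20.8 FPKM and HP at 123 FPKM in the male heart against 0 and 0.155 FPKM in the female heart. In the marmoset testis values they were at 14.8 and 70.7 FPKM. APOH stood at 15.6 FPKM in the male heart and 12753 FPKM in the male liver, and AHSG at 9.75 and 16421 FPKM. The source of these transcripts outside liver was not tested, so they are not read as a sex difference of heart or kidney. In kidney, TMEM238 (65.6 against 2.14 FPKM) and HP (40.7 against 0.401 FPKM) were higher in the male, LST1 was at 25.3 FPKM in the male and listed at 0 in the female, and SCGB2A1 (0.780 against 7.60 FPKM) and UBE2Q2 (2.61 against 14.3 FPKM) were higher in the female.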

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

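The tests of a female source of RNA, of lower Y-linked expression in kidney, of the scaling, of a single scale factor and of dilution were chosen after the results they address had been seen. The tests of gene length, of a library or animal difference and of failed estimates were chosen before theirs were.

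Sex differences of opposite direction in liver and kidney drew attention to 2 rat genes. Prlr, the prolactin receptor, was higher in the female liver (1.06 FPKM in the male, 179 FPKM in the female, -6.45 log2) and higher in the male kidney (21.0 against 2.41 FPKM, 2.69), so that the male minus female difference in liver lay at -9.14 relative to kidney. Car3, a carbonic anhydrase, was higher in the male liver (2663 against 195 FPKM, 3.77) and in the female kidney (3.22 against 79.2 FPKM, -4.25), a difference of 8.01 between the tissues. With 1 animal per sex, the difference was not tested for either gene.

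The marmoset library labelled male kidney held little Y-linked RNA, with 6 of the 11 Y-linked genes above 0 in heart and liver listed at 0 and DDX3Y at 37.2% of their mean. A scaling that lowers all values of the library is argued against, since its median-ratio factor was 1.09 against the other libraries of the species. RNA mostly from a female might account for it, in which case the female excess of ZFX, DDX3X, KDM6A and USP9X should shrink in kidney. After rescaling, their median excess was 0.64 log2 in kidney, 1.29 in heart and 1.21 in liver, which is 51.6% of the mean of the latter, between the bounds set for a female source and for none. A kidney that expresses Y-linked genes less than the other organs predicts no such shrinkage and meets the same value of 51.6%, so a female source and a tissue difference cannot be told apart with 1 male kidney.

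More genes were higher in the male than in the female marmoset in all 3 tissues. A single scale factor per library is argued against as the whole cause, since 73.9% of the genes that differed in all 3 tissues after rescaling were male-higher. A gene length bias could also favour one library. That check covers the 67.8% of the genes (812 of 1197) that matched a gene model. Genes without a symbol could not match, and of the 868 with a symbol, 93.5% did. Among the matched genes the male-higher share was 96.3%, 86.7% and 31.0% in the shortest, middle and longest of 3 equal groups by span. These shares lie past both bounds set beforehand for such a bias, so the matched genes go with it. The check was scored as undecided for its coverage, by a limit that was not part of the prediction, and the unmatched genes stay open. A difference of library or animal was to be argued against by a correlation over 0.4 with the rat, and Spearman's rho across 7748 shared symbols, which are not independent replicates, was 0.505. That bound was wrong, because each species has 1 male and 1 female and a library bias that follows a property of the gene gives such a correlation too, so a library or animal difference and a sex difference cannot be told apart.

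Spermatid transcripts were few in the marmoset testis values, with TNP1 at 0.169 FPKM against 3396 FPKM in rat testis, GAPDHS at 0.279 against 1072 FPKM, LDHC at 1.89 against 991 FPKM and AKAP4 at 0.408 against 381 FPKM, in tables normalized separately. Failed estimates that leave an exact 0 in the column are argued against. Of the 1165 marmoset counterparts of genes that stand out in rat testis, 1.03% were listed at 0, while 41.8% were below 1 FPKM. The column stands for 3 samples, and 2.63% of all its genes were listed at 0. A failure in only some of the samples might leave a value above 0, so failures of that kind stay open. Dilution by RNA of another tissue was to be judged by whether the germ cell lists fall alike. The spermatid list lay lower than the meiosis list by -6.35 log2 in the marmoset relative to the rat (11 and 13 shared genes). On log2(FPKM + 1) a gene can fall only as far as its rat level allows. Most meiosis genes were lower than the spermatid genes in rat testis, so this difference cannot decide on dilution. The Sertoli and steroidogenic lists were higher by 1.75 and 1.90 over 7 genes each. A difference in the state of the animals' testes or between the species may remain and was not tested, as the labels used give no group for it.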

How the results depend on the processing

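Chosen after the data had been seen were the results without mitochondrial and Y-linked genes and those without the library labelled male kidney or both kidney libraries of the marmoset. So were the testis filter at 2 libraries and the list tests after rescaling. All other alternatives were planned. Counts were within 1.5 times, and other values within their spread, in 127 of 156 combinations of a result and an alternative, and moved further in 29. Rescaling turned the larger side of the split in marmoset liver (2504 higher and 2003 lower, then 2100 and 2341), marmoset testis (3104 and 4034, then 3907 and 3236), rat kidney (1673 and 1751, then 1916 and 1471) and the wallaby (1423 and 3229, then 2118 and 2005). For named genes under all alternatives, and for lists under rescaling and without mitochondrial and Y-linked genes, 2191 of 2217 combinations kept direction and side of the threshold, and 26, over 10 named genes, lost the call in the same direction. The list tests with an estimated correlation, which kept none of the 67 list calls, are not among these. With 2 residual degrees of freedom that mode could pass hardly any list, so it does not decide whether the calls hold.

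Without the animal block (in the testis fit, the sex block), limma called 2975 genes in place of 5103 in marmoset heart, 1719 in place of 3282 in kidney, 2494 in place of 4507 in liver and 3611 in place of 7138 in testis. The rat counts stayed within 1.5 times (4502, 2831 and 4133 in heart, kidney and liver). In the somatic fits the block removes a difference between the animals that is shared by the tissues. In the testis fit it pairs no tissues of one individual for certain, since the column also stands for a second male.

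Leaving out 1 library at a time gave 3653 to 5053 genes in marmoset heart, 1378 to 3293 in kidney, 3476 to 4271 in liver and 4367 to 6703 in testis, and 4103 to 4852, 2340 to 3150 and 3969 to 4460 in rat heart, kidney and liver. The lowest in marmoset kidney and testis were without the library labelled male kidney. Without the female kidney library, marmoset kidney had 1506 genes. Such fits leave a tissue with 1 library, assumed to vary like the others. Without both kidney libraries marmoset testis had 5322 genes, and with the filter at 2 libraries 7003.

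A pseudocount of 0.1, which widens differences of low genes by construction, raised the counts to 1813 in marmoset testis by gaps, 464 in marmoset ovary, 4340 in rat testis, 485 in rat ovary and 564 for the rat sexes. It moved the rat X partner medians to 0.46 in heart, 0.42 in kidney and 0.41 in liver. Rescaling by median ratios moved the X partner medians to 0.76, 0.52 and 0.72 in marmoset heart, kidney and liver and to 0.38, 0.62 and 0.52 in the rat. With genes of at least 5 FPKM they were 0.57 in marmoset heart and 0.44 in rat heart, and 10 of 15 marmoset and 3 of 6 rat Y-linked genes were restricted to testis, as fewer genes enter. The cause was not tested for the shifts of the X partner medians. Genes that differ between the sexes in all tissues numbered 2334 without kidney in the marmoset, and 840 without heart and 504 without liver in the rat, as fewer tissues have to meet the condition. List tests past the threshold numbered 67 with the preset correlation, 74 after rescaling, 66 without mitochondrial and Y-linked genes, and 0 with an estimated correlation.

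Planned but not run were the frontal cortex and cerebellum results, since no column was assigned to them, and marmoset testis individual 1 alone, since the testis column is pooled. The depth is unknown, so values near 0 and exact zeros carry no counting limit. In simulated data limma recovered 17.9% to 35.8% of genes changed by a log2 of 1 in the somatic contrasts and 1.49% in marmoset testis. There 200 genes were changed, the others had no tissue difference, and a call needed an estimated change of at least 1. These rates therefore need not hold in the real contrasts, where many more genes differ.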

Other observations

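The comparisons between species and between tissues and the epididymis test in this part were chosen after results had been seen. The gene list values were planned. Heart, kidney and liver genes called by limma in both the marmoset and the rat were counted over 8050 shared symbols. In heart 711 symbols were higher in both species against 203 expected from independent lists, in kidney 533 against 119, and in liver 803 against 255. Opposite calls were fewer than expected: 39 higher in marmoset and lower in rat heart and 74 the other way, against 231 and 325, with 40 and 29 against 118 and 112 in kidney and 81 and 36 against 273 and 205 in liver. Among these, VNN1, a pantetheinase, was at -3.90 in marmoset and 3.49 in rat heart, and at 5.96 in marmoset and -2.45 in rat liver. GATM, of creatine synthesis, was at 2.58 and -2.67 in heart, BMP7, a growth factor, at 3.26 and -3.08 in heart, SLC16A7, a monocarboxylate transporter, at 2.56 and -3.86 in heart, SLC28A2, a nucleoside transporter, at 2.92 and -3.53 in kidney, and SLC6A13, a GABA transporter, at -2.90 and 4.35 in liver. The difference between the species was not tested for these genes.

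Genes higher in testis than in liver were shared between the wallaby and the rat in 570 cases, 55.7% of the 1024 wallaby symbols, against 137 expected. Between the wallaby and the marmoset 114 were shared, 11.9%, against 86.3 expected, and between the rat and the marmoset 207, 12.8%, against 142. Of 7 heat shock genes 2 were higher by limma in the marmoset testis values, HSP90AA1 at 4.28 and HSPH1 at 2.52, and the list did not pass camera (adjusted p = 0.126; adjusted p = 0.720 with an estimated correlation). Its median was 1.59 relative to all genes of the fit (percentile 99.9 of matched random lists). Between the marmoset sexes their relative median was -1.35 in heart, 0.30 in kidney and -0.97 in liver. Sex hormone receptors had a median of 0.98 in rat ovary (percentile 99.4), with Esr2 at 1.55 and Prlr at 1.33, and of 0.43 in marmoset ovary (percentile 86.4), with ESR2 at 1.89 and PGR at 1.49. Cerebellar neuron genes in marmoset testis were higher in 2 and lower in 1 of 5 (camera adjusted p = 0.111).

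Male minus female differences were correlated between tissues across genes, which are not independent replicates, with Spearman's rho between 0.693 and 0.753 over 13509 marmoset genes and between 0.455 and 0.577 over 12739 rat genes, on rescaled values. Symbols higher in the male in every tissue of both species numbered 32 on rescaled values against 3.66 expected from independent lists, among 480 in the marmoset and 59 in the rat, and 52 against 8.57 on the deposited values. CEBPB, CEBPD, CHCHD10, RPL13 and RPL36 were among them. Symbols higher in the female in both numbered 7 against 0.843, among them ANP32A, FBXO3 and ZFP91. With 1 male and 1 female per species, a library bias that follows a property of the gene would give such overlaps too. These counts cannot tell such a bias from a shared sex difference.

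Several genes that stood above the other tissues in the marmoset testis values encode secreted proteins known from the epididymis, the duct in which sperm mature: SCGB1D1 at 7143 FPKM, DEFB126 at 441 FPKM, DEFB129 at 342 FPKM, OBP2A at 267 FPKM, and CLPSL1 and CLPSL2 at 73.0 and 51.2 FPKM. A candidate explanation is epididymal tissue in the testis samples, which should bring its other abundant transcripts. Of 29 further epididymal genes listed before the test, 14 were in the table and 3 of these, 21.4%, reached 1 FPKM in testis: DEFB121 at 8.00, LCN6 at 2.88 and BSPH1 at 1.53 FPKM. CRISP1 and GPX5, abundant in the epididymis, were at 0.116 and 0.114 FPKM. The median of the 4 measured members was 1.06, above the 0.36 that is the median of matched random lists (percentile 83.1). Because the list leaves out the high genes that prompted it and few of its members were in the table, it excludes nothing, and epididymal tissue stays open as a source. No other source was tested.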
